A study of Mus musculus with 2 samples.

How the data were processed

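RNA of adherent, thioglycollate-elicited peritoneal macrophages was hybridised to 2 Affymetrix arrays, 1 per genotype. Per the labels' protocols, cDNA was made from 100 ng of total RNA and 5.5 ug of it was labelled. How many mice gave each RNA, and their sex, are not given in the sources used here.

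The deposited workbook holds an RMA intensity on a linear scale for 41345 probesets, made by the authors with Affymetrix Expression Console 1.2.1 and RMA, per the submitters' processing notes and the file headers. The series matrix deposited by the authors holds log2 values of the same signals, which differed from log2 of the workbook by at most 5e-05. The workbook's fold column, deposited by the authors, is a signed ratio of the brighter over the dimmer signal and was recomputed from the signals. A further sheet holds probesets the authors selected. Library files and the genome build are not given in the sources used here. Of 22919 probesets whose symbol is also a RefSeq gene name in GRCm38.p6, 96.2% overlapped that gene, and the deposited coordinates are printed as they stand.

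Gene names came from the deposited annotation. Of 33641 main probesets, 26563 had 1 symbol, 124 several and 6954 none, and 8 rows with displaced annotation were left unnamed. The remainder included 5331 intron controls and 2306 probesets with blank annotation. The probeset with the highest mean signal stood for each of 24315 genes, of which 1562 had several. In 412 genes with a pair of probesets above the floor, these disagreed by a median of 0.15 on the log2 scale, with a 95th percentile of 0.61, and their differences correlated with r = 0.30. A gene was kept when its brighter array reached the median of all named genes (log2 7.31, signal 159), which left 12158.

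The following were fixed before the data were examined: the floor, fold sizes of 1.5 and 2, 37 gene lists, 14 marker lists and the rule for named genes. Named genes are Hdac11, the monocyte chemoattractants, the 12 highest and 12 lowest genes above the floor, and of each list described the members at 1.5-fold (at most 4) or otherwise the 2 furthest from 0. Predicted, clone-named, olfactory, vomeronasal, small RNA and antigen receptor segment names were left out of the 12, which passed over 28 lower and 4 higher genes. Xist, named beside the Y-linked genes, was chosen after its values were seen. A list's median was set against 10000 random lists of equal size matched in 20 bins of mean signal, its central range leaves out 2.5% of them at either end, and a list with fewer than 4 members above the floor got no percentile. Of 761 list entries, 746 were measured. No test between genotypes was possible with 1 array per group.

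Steps were tested on simulated data made by permuting the differences of the 12158 genes within signal bins. Of 200 genes shifted 2-fold, 99% were recovered at 1.5-fold. Of 420 simulated lists, 4.29% lay outside the central range with no shift, 55.2% with a shift of 0.1, 89.8% with 0.2 and 98.3% with 0.3 on the log2 scale. Permuted differences hold no spread between animals and no co-regulation of genes, so these rates check the steps alone. Alternatives covered the source of the values, scaling (median, loess, quantile), the summary of probesets, the floor, an offset of 16 and the list statistics. Background correction and probe-level steps were not varied, since only processed values were analysed here.

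The decimals of the signals were examined after some named genes were seen to have equal decimals on both arrays. Among probesets with signals above 50 on both arrays, the arrays differed by a whole or half-integer unit, to within 0.001 and leaving out equal signals, in 5.64% of 12921 probesets with an odd number of probes, 0.383% of 15412 with an even number, and 0.491% after shuffling. Of the 43 with 1 probe, 88.4% did so. In all, 466 probesets had exactly equal signals, Cd209a among them. No probeset was left out for this.

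Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.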

Results

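Transcript levels were measured in macrophages that thioglycollate, an irritant injected into the abdomen, had drawn into the peritoneal cavity of C57BL/6 mice. The cells came from mice carrying an HDAC11 knockout and from wild-type mice, were kept in culture overnight without treatment, and the adherent cells gave the RNA. HDAC11 is a histone deacetylase, and the series concerns secretion of MCP-1, the monocyte-attracting chemokine encoded by Ccl2. There was 1 array per genotype, so no difference below has a replicate check or a p-value, and the number of arrays limits the precision. Values are the authors' RMA signals, and differences are log2 values of the knockout-labelled minus the wild-type array. Of 24315 genes named by a single symbol, 12158 reached the signal floor of 159, and the arrays correlated across all 24315 genes with r = 0.995, where genes are not independent replicates.

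The targeted gene was not lower on the array labelled knockout. The Hdac11 probeset (17460879, chromosome 6, 91156665 to 91174692, 28 probes) gave 134.5 on the wild-type and 147.2 on the knockout-labelled array, a difference of 0.13, and both signals lay below the floor. A probeset on the opposite strand with the same symbol gave a difference of 0.05. Whether probes lie inside the deleted part of the gene was not given in the sources used here, so this signal neither checks nor contradicts the label, and every direction below rests on the label alone. The genome build is not given in the sources used here; coordinates are those of the deposited annotation.

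Ccl2 and its neighbour Ccl7, both encoding chemokines that attract monocytes, were lower on the knockout-labelled array. Ccl2 (probeset 17254041, chromosome 11, 82035571 to 82037453) gave 2672 on the wild-type and 1516 on the knockout-labelled array, a difference of -0.82 or 1.76-fold. Ccl7 (probeset 17254047, chromosome 11, 82045712 to 82047525) gave 1047 and 553, a difference of -0.92 or 1.89-fold. Among genes of like mean signal these differences stood at the 0.164th and 0.329th percentiles. The related Ccl8 went the other way below the floor, with 77.3 on the wild-type and 154.9 on the knockout-labelled array, and Ccl12 gave 18.4 and 19.1. The median of the 2 members above the floor was -0.87.

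Other chemokines were also lower on the knockout-labelled array. The interferon-gamma-inducible Cxcl9 gave 238.7 and 99.0 (-1.27, the dimmer signal below the floor), Ccl22 360.2 and 190.3 (-0.92), and the B cell attractant Cxcl13 1539 and 1019 (-0.60). Of the 7 CXC and other chemokines above the floor 6 were lower, with a median of -0.18 at the 1.23rd percentile of 10000 random lists matched on mean signal. Quantile normalization of the arrays to each other put that median at -0.08 and the 5.74th percentile, and leaving out the largest member put it at the 3.73rd. The other CC chemokines had a median of -0.03 (percentile 29.9) and a mean of -0.18 (percentile 1.24). Such percentiles describe these arrays; genes of a list are co-regulated, so a list outside the central range is no test of genotype.

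Among genes above the floor, 11 were higher and 33 lower by 2-fold or more on the knockout-labelled array, and 66 were higher and 123 lower by 1.5-fold or more. Lower genes made up 65.1% of the genes at 1.5-fold, and 48.0% after quantile normalization. Without small RNA, predicted, clone-named and antigen receptor genes, a choice made after seeing the data, 8 genes were higher and 9 lower by 2-fold, and 52 were higher and 58 lower by 1.5-fold (52.7% lower).

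**Figure D1:**
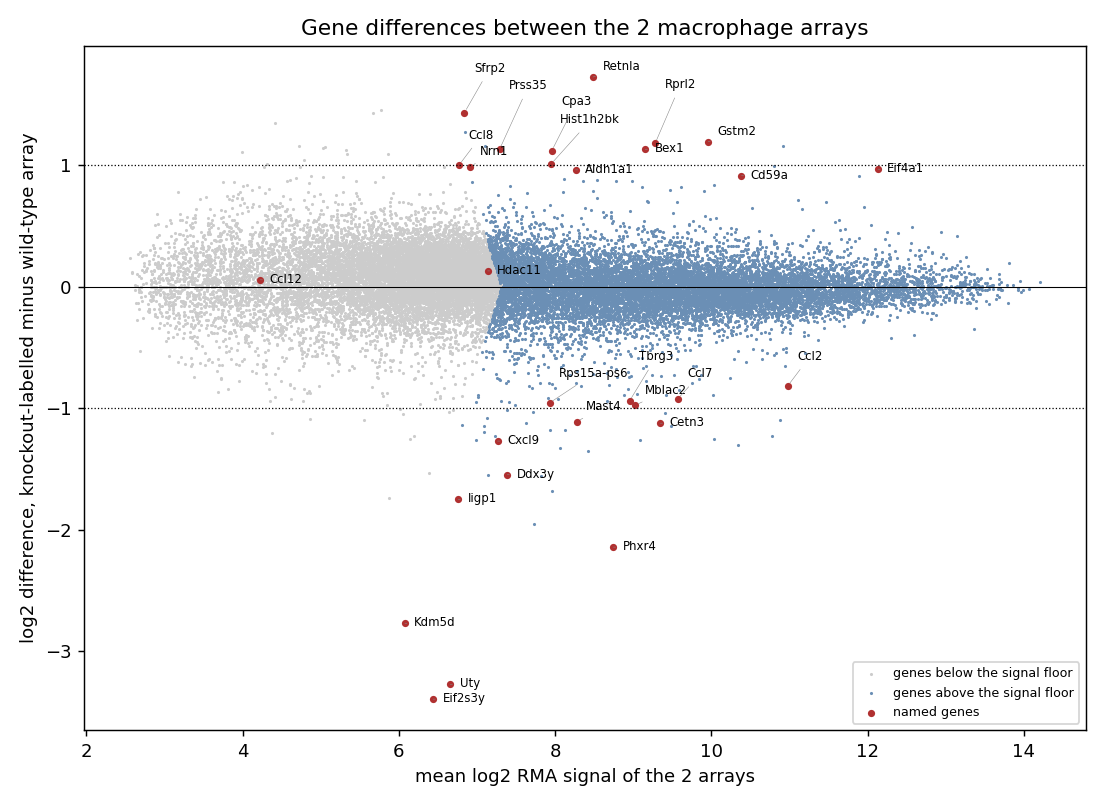
Log2 difference (knockout-labelled minus wild-type array) against the mean log2 RMA signal of both arrays for each of 24315 genes, with genes above the signal floor in blue, those below it in grey, and named genes in red. Dotted lines mark a 2-fold difference, Ccl2 lies at -0.82 and Hdac11 at 0.13.

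The lowest genes relative to wild type included 4 on the Y chromosome. Of 10 genes above the floor with any probeset placed there, these 4 were lower by 1.5-fold and 2 were higher, Erdr1 (0.71) and LOC100039659 (0.76), both chosen after their values were seen. The 10 are not all Y-linked: the values of Gapdh and Rmi1 came from probesets on other chromosomes. The probesets of LOC100039659, LOC382133 and Mid1 were not unique by the deposited annotation. Whether these genes or Erdr1 lie on Y alone was not examined. Eif2s3y gave 281.4 and 26.8 (-3.39), Uty 313.8 and 32.5 (-3.27), Kdm5d 176.4 and 25.9 (-2.77), and Ddx3y 286.2 and 98.0 (-1.55). The knockout-labelled signals of all 4 lay below the floor, so the sizes of their differences are uncertain. With 16 added to each signal Eif2s3y gave -2.80, Uty -2.77 and Kdm5d -2.20. Xist, the RNA of the inactive X chromosome, was bright on both arrays at 8688 and 8458 (-0.04). Apart from the Y-linked genes and Cxcl9, the 12 lowest genes held the interferon-inducible GTPase Iigp1 (-1.75, or -1.52 with 16 added), Phxr4 (-2.14), the centrosome gene Cetn3 (-1.12), Mast4 (-1.11), Mblac2 (-0.98), Rps15a-ps6 (-0.96) and Tbrg3 (-0.94). The mean of the 2 probesets of Mast4 gave -0.53, so its other probeset was not lower.

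The highest was Retnla, a secreted product of alternatively activated macrophages (probeset 17326069, chromosome 16, 48842552 to 48844461), at 197.3 on the wild-type and 652 on the knockout-labelled array (1.72, 3.30-fold). It was followed by Sfrp2 (1.43), an extracellular Wnt inhibitor, and the glutathione S-transferase Gstm2 (1.19). Rprl2 (1.18), Prss35 (1.13), Bex1 (1.13), the mast cell carboxypeptidase Cpa3 (1.12), Hist1h2bk (1.01), Nrn1 (0.99), Eif4a1 (0.97), the retinaldehyde dehydrogenase Aldh1a1 (0.96) and the complement regulator Cd59a (0.91) completed the 12. The wild-type signals of Sfrp2, Prss35 and Nrn1 lay below the floor, which leaves the sizes of their differences uncertain. By the deposited annotation the probesets of Rprl2, Hist1h2bk and Eif4a1 were not unique. Averaging the 2 probesets of each gene moved Sfrp2 to 0.81 and Eif4a1 to 0.40. The other probeset of Sfrp2 thus differed less, and that of Eif4a1 went the other way. In the alternative activation list Chi3l3 (0.82, the dimmer signal below the floor) was also higher, but the arginase gene Arg1 was lower (-0.71), and 7 members were higher and 7 lower, with a median of 0.03 (percentile 75.4) and a mean of 0.13 (percentile 99.3).

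Classical activation genes were lower in 9 of 12 cases, with a median of -0.13 (percentile 1.55), and Irg1, which makes itaconate, gave -0.76 with its dimmer signal below the floor. Immediate early genes were lower in 11 of 15 cases (median -0.14, percentile 0.21), including the transcription factor Egr1 (-0.68). With the floor at the 75th percentile of signal neither list stayed outside the central range (5 classical activation genes, percentile 4.29; 9 immediate early genes, percentile 3.61). Adhesion and actin genes were lower in 16 of 20 (median -0.14, percentile 0.01), including Itgb7 (-0.55) and Thbs1 (-0.55). Genes of the unfolded protein and amino acid stress response were lower in 13 of 16 (median -0.10, percentile 1.80), with asparagine synthetase Asns at -0.65; after quantile normalization this median was -0.01 (percentile 17.8), and the list lay outside the central range in 12 of 16 alternatives. On the same arrays the 5331 intron control probesets had a median difference of -0.36, and 1764 of them were lower by 1.5-fold.

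**Figure D2:**
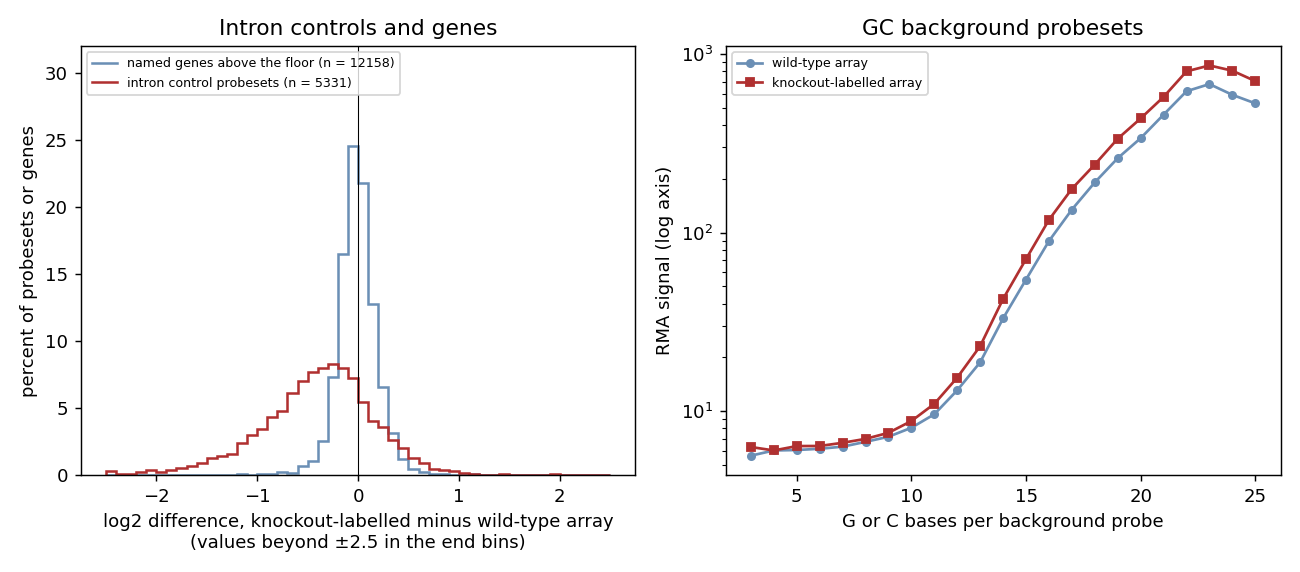
Left, percent of probesets or genes per 0.1 of log2 difference (knockout-labelled minus wild-type array) for 5331 intron controls (red, median -0.36) and 12158 genes above the floor (blue, median -0.01). Right, RMA signal on a log axis of 23 background probesets by G or C bases per probe, where those with 13 to 25 lie a median of 0.37 higher in log2 on the knockout-labelled array.

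All 6 replication-dependent histone genes above the floor were higher (median 0.35, percentile 99.99), with Hist1h1b at 0.43 and Hist1h2bb at 0.43. Ribosomal protein genes were higher in 16 of 21 (median 0.14, percentile 99.99), led by Rpl32 (0.32), and the 17 with unique probesets gave 0.07 (percentile 93.9). Respiratory chain genes were higher in 13 of 20 (median 0.10, percentile 99.9), with Cox4i1 at 0.46 and Ndufa1 at 0.40. Across genes the difference was lower the longer the genomic span (Spearman rho -0.241), from a median of 0.07 in the 1216 genes of shortest span to -0.08 in the 1216 of longest span. With that trend removed, also chosen after seeing the data, these 3 lists had medians of 0.30, 0.08 and 0.11.

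**Figure D3:**
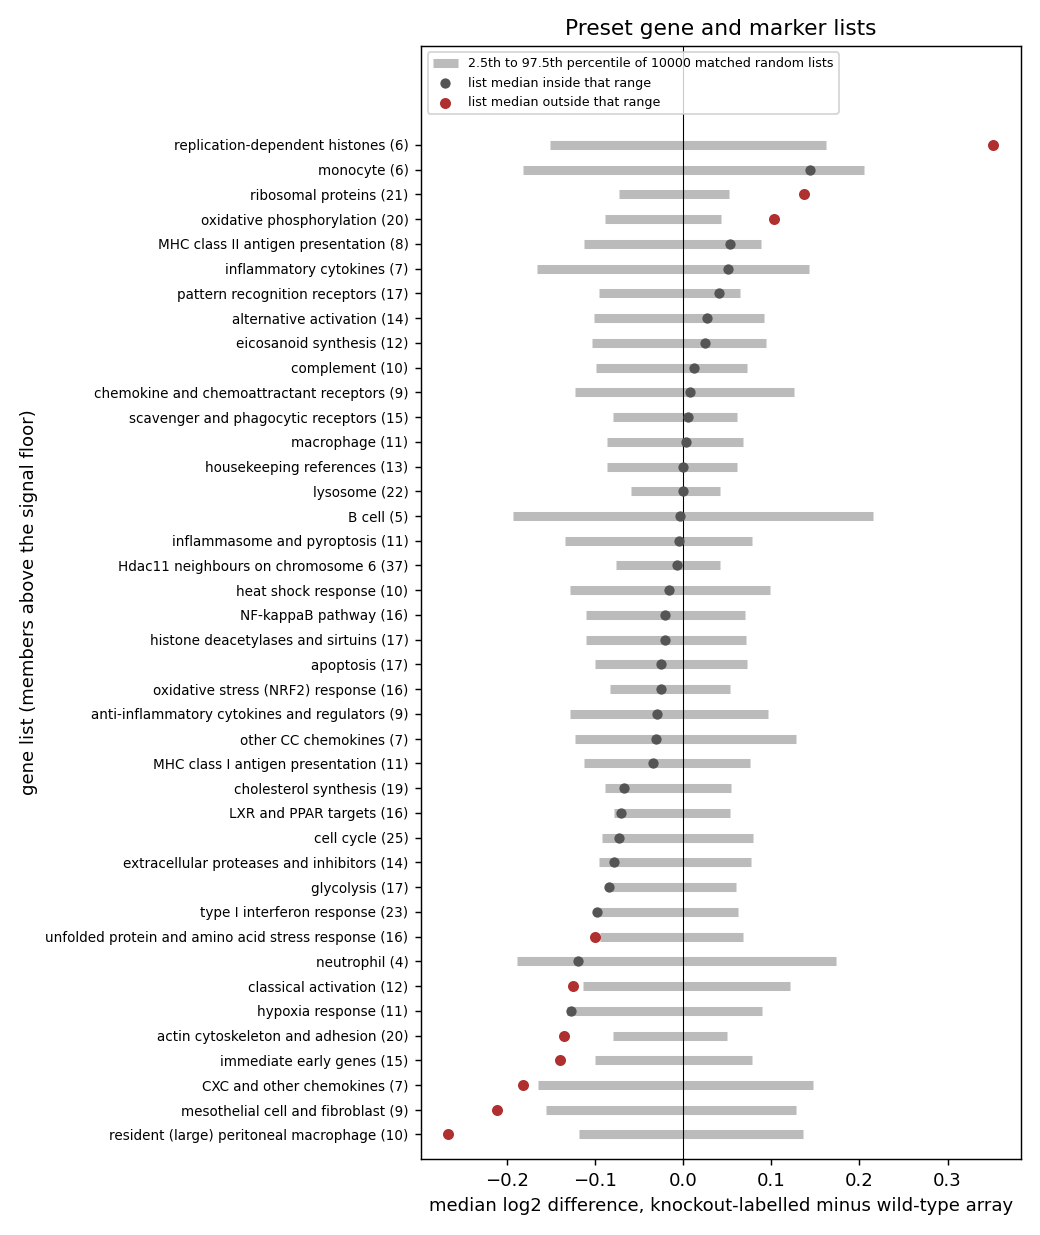
Median log2 difference (knockout-labelled minus wild-type array) of each preset list with a percentile, other than the sex-linked list, against the range of 10000 random lists matched on mean signal, without the outer 2.5% at either end (grey bars); the number of members above the floor is in brackets. Red points lie outside the bar, from resident peritoneal macrophage markers at -0.27 to replication-dependent histones at 0.35.

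Macrophage identity genes had a median of 0.00 (percentile 67.7), with Mertk at 0.27 and Itgam at -0.17. Markers of resident peritoneal macrophages were lower in 8 of 10 (median -0.27, percentile 0.01), or by a median of -0.12 over all 13 without a floor (percentile 0.75), including Selp (-0.82) and Cxcl13, which the chemokine list also holds, and mesothelial and fibroblast markers in 8 of 9 (median -0.21, percentile 0.335), including Pdgfra (-0.52). These moved in the same direction as Ccl2, Ccl7, Ccl22 and Cxcl9. Monocyte markers had a median of 0.14 (percentile 90.8), 4 neutrophil markers -0.12 (percentile 10.3) with S100a8 at 0.89, which turned to 0.17 (percentile 96.3) over all 15 without a floor, and B cell markers 0.00 (percentile 44.6). Too few markers reached the floor for a percentile in the other lists. Their medians were 0.06 for 3 eosinophil genes, 0.09 for 2 plasma cell genes, 0.30 for 2 T cell genes, 0.01 for 2 dendritic cell genes and -0.27 for 2 endothelial genes. Single genes represented mast cells (Cpa3), NK cells (Prf1, -0.27) and platelets (Pf4, 0.00).

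Of 42 lists with a percentile, 11 lay outside the central range, 8 lower and 3 higher, where 2.1 would do so by chance if genes were independent. The medians of the other 31 lay between -0.13 and 0.14. Type I interferon genes had -0.10 (percentile 3.04), with 17 of 23 lower, although Ifit3 was higher (0.53); this list lay outside the central range in 9 of 16 alternatives. Glycolysis genes had -0.08 (percentile 2.81) and hypoxia genes -0.13 (percentile 2.84), with Vegfa at -0.40. Inflammatory cytokines had 0.05 (percentile 77.8), with Tnf at -0.38, and anti-inflammatory regulators -0.03 (percentile 42.7), with Il1rn at -0.51. The other histone deacetylases and sirtuins had a median of -0.02 (percentile 49.8), and none of the 17 reached 1.5-fold. The preset list of Hdac11 neighbours on chromosome 6 had a median of -0.01 (percentile 62.8). It also holds more distant genes, such as Rpl32, which starts at 115805505 against 91156665 for Hdac11. Mgll (0.82), a monoglyceride lipase, was the only 1 of 65 genes above the floor within 5 Mb of Hdac11 to reach 1.5-fold. That share of 1.54% was close to the 1.55% of all genes above the floor.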

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

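Of the tests in this part, those on X-linked escape genes and, for the intron controls, on nuclear RNAs were set before their results were seen (the value of Xist, a member of the latter, was known), and the others only afterwards. Signals outside the comparison drew attention in 3 places. The 13 background probesets with 13 to 25 G or C bases per probe had a median difference of 0.368, higher on the knockout-labelled array. The intron control probesets, each pair of signals counted a single time, had a median of -0.364. Unannotated probeset 17341711 gave 9.53 on the wild-type and 80.9 on the knockout-labelled array. Both signals lay below the floor, and the background probeset with 11 G or C bases gave 9.60 on the wild-type array, so the 8.49-fold ratio is of deposited signals and no measured fold of a transcript.

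The Y-linked genes Eif2s3y, Uty, Kdm5d and Ddx3y were lower on the knockout-labelled array, while Xist was bright on both. Erdr1 and LOC100039659, whose probesets are also placed on Y, were higher. The probeset of LOC100039659 was not unique by the deposited annotation, and whether either gene lies on Y alone was not examined. Genes of like mean signal did not share this fall of the Y-linked genes, with a median difference of 0.0795. RMA aligns the signal distributions of the arrays, so that median cannot show whether dim signal was generally lost before that step. RNA of male cells in the wild-type sample with few or none in the other remains a candidate explanation. It predicts higher X-linked escape genes on the knockout-labelled array, and Kdm6a, Eif2s3x, Kdm5c and Ddx3x had a median of 0.0241 with an SD of 0.0691. The size of the predicted rise is unknown, because the share of male cells is not given and Xist was bright on both arrays. The escape genes therefore decide neither for nor against male cells in the wild-type sample. The sex of the mice is not given in the sources used here and stays open.

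Intron controls were lower, with a median of -0.36 against -0.01 for genes above the floor. Genomic DNA in the wild-type RNA is argued against by olfactory receptor genes, with a median of 0.0637, against -0.42 for introns in the same range of signal. A lower background on the knockout-labelled array is argued against by the 23 background probesets, none of them lower there, with a median of 0.330 (SD 0.145). The background did differ, being higher on that array in 22 of the 23, and whether this bears on the intron controls was not tested. Less nuclear RNA in the knockout-labelled sample may account for the lower intron controls. The 7 nuclear-retained RNAs above the floor were all lower, with a median of -0.221, beyond the bound of -0.182 set for the test. Their SD was 0.301, however, and Xist (-0.04), Malat1 (-0.12) and 6720401G13Rik (-0.14) did not reach that bound. No biological cause of such a shift was tested, and a difference in RNA preparation stays open.

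Ccl2, Ccl7, Ccl22 and Cxcl9 were lower by a median of -0.92 on the knockout-labelled array. Markers of stromal cells (median -0.212, SD 0.155) and of resident macrophages (median -0.266, SD 0.290) were also lower, but by less than -0.92. The nuclear-retained RNAs were lower by less as well (median -0.221, SD 0.301). These chemokines were picked after their low values were seen, whereas the lists were not picked for theirs. The comparison therefore cannot decide whether fewer stromal cells, fewer resident macrophages or less nuclear RNA was the whole cause. A weaker interferon-gamma response stays undecided. Of 9 further inducible genes 6 were lower and 3 higher, at the 5.17th percentile of random lists, short of the 2.5th percentile set for the test. Such a percentile is no test of genotype, and these genes were chosen as ones not yet looked at. Of 10 guanylate-binding and immunity-related GTPases above the floor, assembled after some values were seen, 9 were lower and 1 higher (median -0.25). The HDAC11 genotype and the sex of the mice also stay open and cannot be separated with 1 array per genotype.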

How the results depend on the processing

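With 1 array per genotype, no paired analysis or test was possible. Under the alternatives, a count was taken to stay within 1.5 times the main count, a gene's difference within 1 SD of genes of like mean signal, and a list median within 1 SD of its random lists. By this, 83 values of the main comparison (counts, Ccl2 and Hdac11) stayed and 15 moved; no called value changed sign. Ccl2 lay between -0.79 (quantile) and -0.90 (span trend removed), and Hdac11 between 0.06 (loess) and 0.16 (quantile). Quantile normalization gave 103 genes higher by 1.5-fold. Without a floor, 25 genes were higher by 2-fold, 250 higher and 258 lower by 1.5-fold, and a floor at the 25th percentile gave 121 higher by 1.5-fold. A floor at the 75th percentile left 4 higher and 9 lower by 2-fold, 23 higher and 35 lower by 1.5-fold, and 6 lists apart, from the smaller number of genes. The following were chosen after seeing the data. A floor of 30 gave 23 higher by 2-fold, and 190 higher and 216 lower by 1.5-fold. Without small RNA, predicted, clone-named and antigen receptor names, 9 genes were lower by 2-fold and 58 by 1.5-fold. Without the 10 genes with any probeset on the Y chromosome, Gapdh and Rmi1 among them, 64 were higher and 119 lower by 1.5-fold. With the span trend removed 193 genes reached 1.5-fold, 174 of them among the 189. Of named genes, 1190 values stayed and 9 moved, but changed floors cannot move gene differences. Of list medians, 666 stayed and 143 moved. Adhesion and respiratory chain genes lay apart in all 16 alternatives for lists, unfolded protein genes in 12, CXC and other chemokines and sex-linked genes in 14, and the other 6 such lists in 15. For classical activation and immediate early genes the exception was the floor at the 75th percentile, for ribosomal proteins unique probesets, and for histones, resident macrophage and mesothelial markers a floor that left fewer than 4 members. The neutrophil median turned from -0.12 to between 0.09 and 0.17 without a floor, with floors of 30 or the 25th percentile, and for the mean of its members. Of lists not apart, type I interferon genes became so in 9, hypoxia genes in 4, glycolysis and protease genes in 3 each, LXR and PPAR targets in 2, and other CC chemokines and alternative activation genes in 1 each. The cause was not tested where not stated. Adding 16 moved Eif2s3y, Uty, Kdm5d and Iigp1, whose dimmer signals lay below the floor. Low signal limits every named gene with a signal below the floor, among them these, Ddx3y, Hdac11, Ccl8, Ccl12, Cxcl9, Irg1, Chi3l3, Sfrp2, Prss35 and Nrn1.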

Other observations

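Further gene families were assembled after some or all of their values were seen, so their medians describe genes partly picked for their values and are no test. Of 10 guanylate-binding and immunity-related GTPases above the floor, which interferon-gamma induces, 9 were lower on the knockout-labelled array (median -0.25), including Gbp2 (-0.46) and Gm4951 (-1.19); Gbp7 was higher (0.21). Of 15 glutathione S-transferases 12 were higher (median 0.17), including Mgst1 (0.44) and Gstk1 (0.33), while Gstp2 was lower (-0.48). Of 13 iron genes 7 were higher and 6 lower (median 0.02), and the transferrin receptor Tfrc (0.66) and the iron exporter Slc40a1 (0.78) were both above 1.5-fold higher. All 4 immunoglobulin genes above the floor were lower (median -0.85), including Ighg3 (-1.95) and Ighm (-0.89), whereas the B cell marker list had a median of 0.00. Of 12 mast cell genes only Cpa3 reached the floor, and Tpsb2 was higher below it (0.77).

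The authors' deposited table of selected probesets held 2816, with 503 higher and 2313 lower. Intron controls made up 62.5% of the authors' deposited table (1760 probesets), and 479 were main probesets with 1 symbol. Applying the lowest brighter signal (30.1) and the smallest fold in the authors' deposited table to all probesets returned 2816. The authors' deposited table gives Ccl2 a fold of -1.76 and Ccl7 -1.89.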
